A study of Drosophila melanogaster with 4 samples.

How the data were processed

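Chromatin from last-stage (L3) larvae of the wild type strain Oregon-R of Drosophila melanogaster was immunoprecipitated with a rabbit antibody against histone H3 monomethylated at lysine 79 (H3K79me1) and sequenced. The series held 4 libraries, 2 ChIP replicates and 2 input replicates. The labels gave an antibody reference page whose address names the dimethylated form, while the antibody name and target were the monomethylated form, and the labels' target was used here. Nothing in the labels says that the replicates came from separate cultures. All p-values therefore rest on positions, blocks or regions of the genome within these libraries, not on a spread between animals.

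Bowtie 0.12.7 was named in the submitters' processing notes. The coordinates were of FlyBase release 5, per the file headers. The 3 files analysed were a list of regions for each ChIP replicate and a combined list for the series. The authors deposited for each region a start, an end and a score, and each region was called either enriched or depleted. The caller, its threshold, the use of the input libraries and the way the replicates were combined were not given in the sources used here. The input libraries had no list of their own in the files used here, so no background value could be set beside the ChIP lists. Read totals per library were not used here, so the depth behind each region was unknown and no counting interval was given for a region.

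The log base of the score was read from the values. After subtraction of 1 constant per list, each enriched region's score equalled log2 of a ratio of whole numbers with a denominator of at most 60000, within a relative tolerance of 1e-13, in 100% of regions of each list. With the constant shifted on purpose, at most 0.0157% of scores did. The constants were 0.12, 0.33 and 0.23 for replicate 1, replicate 2 and the combined list. Each was the one that gave the smallest whole numbers among those tried, since a constant that differs by log2 of a ratio of whole numbers gives such ratios too. What the whole numbers counted is not stated, and only ratios in lowest terms can be read, so no tag counts were derived. The score is the authors' and was used to describe, rank or filter regions within a list. Its ranks were also compared between the replicates, and its medians between X and the autosomes within each list.

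The numbers of regions, their widths and the length they covered were computed per list from enriched regions only. Replicate overlap was measured as the Jaccard index of covered base pairs and as the share of regions overlapped by at least 1 bp. Both were tested 1-sided against 10000 independent circular shifts of replicate 2 within each sequence. Of the 14 sequences, those without regions, such as Uextra, took no part. The covered share of X was divided by that of the 4 large autosome arms (2L, 2R, 3L and 3R) and tested 2-sided by 10000 permutations of 500 kb blocks. The same was done for chromosome 4 with 100 kb blocks. Ratios averaged over replicates were geometric means. No p was given for the 6 heterochromatic sequences, by a rule fixed beforehand that leaves out sequences with few blocks, and their pooled share was not tested. Scores of overlapping regions were compared by Spearman's rho with 10000 permutations, each region of replicate 1 being paired with the replicate 2 region it overlapped most. The smallest p that 10000 draws can give is 0.0001. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

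The regions named were the 10 with the highest score and the 5 widest of the combined list, the rule set for the case that no gene positions of the right build were at hand. Groups, the tests of the overlap, the combined list, the covered shares and the score agreement, and most of their alternatives were fixed before the data were examined. The comparison of scores between X and the autosomes was added afterwards. The alternatives were another overlap rule, regions at or above the median score of each list, regions within 1 kb merged, a minimum width, the main arms only, each replicate left out and the combined list. Gene coverage, genomic features, position within genes and 33 gene lists were planned as 4 further results and are not analysed here, because the gene table at hand was of release 6 and the regions of release 5.

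Simulated data were used to test the Jaccard index with its shifts and the X to autosome ratio with 500 kb blocks. They were also used for the score difference on X and the reading of whole-number ratios. Spearman's rho, the shares of regions overlapped and the chromosome 4 values were not tested in this way. Lists shifted at random gave a p under 0.05 in 0 of 20 runs. Lists with a known shared part gave that share and a p under 0.05 in 5 of 5 runs. Each such list was a subset of replicate 1, for which the index equals that share by construction. An X to autosome ratio lowered to about 0.5 of its value was recovered in 20 of 20 runs, and random splits of blocks passed in 1 of 20. Smaller changes of the ratio were not simulated. A score difference of 0.1 on X was called in 20 of 20 runs and shuffled scores in 1 of 20. Whole-number ratios were recovered for 2000 of 2000 simulated scores. Copies of 1 score with a small ratio were placed among them, and the search for the constant starts from the most frequent score. The right constant was thus within reach by design. Apart from these copies, no small whole numbers were simulated.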

Results

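The data were lists of genomic regions enriched for H3K79me1 in last-stage (L3) larvae. This mark is placed by the Dot1 methyltransferase, called grappa in flies, and is found over the bodies of transcribed genes. The series held 2 ChIP replicates, each with its own list, and a combined list. Input libraries, 2 in number, entered no comparison of their own.

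Both replicates marked about the same length of the genome in broad regions. Replicate 1 had 6375 enriched regions covering 37.3 Mb, and replicate 2 had 7305 regions covering 37.4 Mb. On the large arms 2L, 2R, 3L, 3R and X, enriched regions took up 31.2% ± 0.0594 (SD, n = 2) of the sequence. The median region was 3617 bp wide in replicate 1 and 3202 bp in replicate 2, and the widest regions reached 81353 and 74935 bp. Regions of at least 10 kb numbered 933 and 856 and held 44.6% and 38.3% of the covered length. Wider regions had higher scores, with a Spearman rho of 0.81 ± 0.0040 (SD, n = 2) between score and width across the regions of a list, which are not independent replicates. No test was made between the replicates.

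The question the replicates answer is whether both libraries marked the same places, and most of the marked sequence was shared. The lists shared 34.1 Mb, which was 91.3% of the length in replicate 1 and 91.2% of that in replicate 2. The Jaccard index was 0.839, against a mean of 0.186 and a highest value of 0.302 among 10000 circular shifts (1-sided permutation p = 0.0001, the smallest they can give). By sequence, the index was 0.826 (3L) to 0.861 (2R) on the large arms and lower, at 0.552, on chromosome 4. On heterochromatic sequences with regions in both lists it ran from 0.426 (2LHet) to 0.886 (XHet), on few regions each. Of the regions in replicate 1, 92.0% (5863 of 6375) overlapped a region of replicate 2, against 44.6% under shifts. Of those in replicate 2, 87.5% (6391 of 7305) overlapped replicate 1, against 42.6% under shifts, and both permutation p were 0.0001.

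Regions found in 1 replicate alone were shorter and had lower scores in the median, with exceptions. Under the 1 bp rule a wider region is overlapped more easily, so part of the width difference is built in. Scores rose with width, and no comparison within widths was made. The 512 such regions of replicate 1 had a median width of 1568 bp and a median score of 0.50, against 3972 bp and 0.79 for its overlapped regions. The 914 of replicate 2 had a median width of 1538 bp and a median score of 0.49, against 3668 bp and 0.75. The highest score among them was 1.02 in replicate 1 and 1.85 in replicate 2, where the highest score of the whole list was 2.02. Borders lay close together in pairs chosen for mutual overlap, a choice that itself favours close borders. Distances for the other matched pairs were not given. Among 4866 pairs that each overlapped by at least 50% of both regions, the median distance was 134 bp between starts and 140 bp between ends. Replicate 1 joined what replicate 2 split in 922 regions, and the opposite held for 591 regions.

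Regions that ranked high in 1 replicate ranked high in the other. Across 5863 matched pairs the Spearman rho of the scores was 0.87 (2-sided permutation p = 0.0001, the smallest possible). Regions are not independent replicates but were permuted as if they were. This p may thus be too small, and it describes these libraries only.

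The combined list held 7596 enriched regions covering 43.7 Mb. Of that length, 78.0% lay in regions of both replicates, 6.64% in replicate 1 alone, 7.21% in replicate 2 alone and 8.17% (3.57 Mb) in neither. It took in 99.99% of the sequence shared by the replicates. Regions overlapping both replicates numbered 4973 and had a median width of 5244 bp and a median score of 0.73. The 1378 regions overlapping neither replicate had a median width of 1251 bp and a median score of 0.35. The shortest region was 1301 bp in each replicate list and 1001 bp in the combined list. That median width was thus below the width of any replicate region. Wider regions also overlap other lists more easily, so these widths and scores do not set the groups apart by themselves. No test was made, since the list comes from the same series.

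X was marked over about as much of its length as the large autosome arms. Enriched regions covered 30.2% ± 0.386 (SD, n = 2) of X and 31.4% ± 0.163 of the autosome arms. The larvae were not said to be sexed, so the number of X copies behind these values was unknown. The ratio was 0.959 over 45 blocks of X and 193 autosome blocks (2-sided block permutation p = 0.599), so a difference was not detected. Among the autosome arms 2R was covered most, at 35.9% ± 0.621, and 2L least, at 26.6% ± 0.374. With regions at or above the median score alone the ratio was 1.04 (block permutation p = 0.717), on the other side of 1.

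Enriched regions covered far less of chromosome 4 than of the large autosome arms, and hardly any of the heterochromatic sequences. Shares were of full sequence length, so sequence that tags cannot be placed in counted as not covered. Regions covered 10.5% of chromosome 4 in replicate 1 and 6.43% in replicate 2, with 46 and 34 regions. The ratio to the autosome arms was 0.261 (2-sided permutation p = 0.0003 over 14 blocks of 100 kb). These blocks are neighbours on 1 chromosome but were permuted as if independent, so the p may be too small. Some 1 Mb autosome windows were covered as little, such as the centromere-proximal ones of 2L (3.75%), 2R (2.69%) and 3L (0.310%). That of 3R was at 38.6%, and medians of the other windows of 2L, 2R and 3L were 29.2%, 38.3% and 32.4%. Each of the 14 blocks lay below the autosome share in both replicates, the highest at 16.8% and 14.8%. The heterochromatic sequences of 2L, 2R, 3L, 3R, X and Y together were covered over 0.724% ± 0.129 (SD, n = 2). XHet stood highest among them at 6.80% ± 0.443, on a sequence of 0.204 Mb. With regions at or above the median score alone the chromosome 4 ratio was 0.114 and the heterochromatic share 0.187%.

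**Figure D1:**
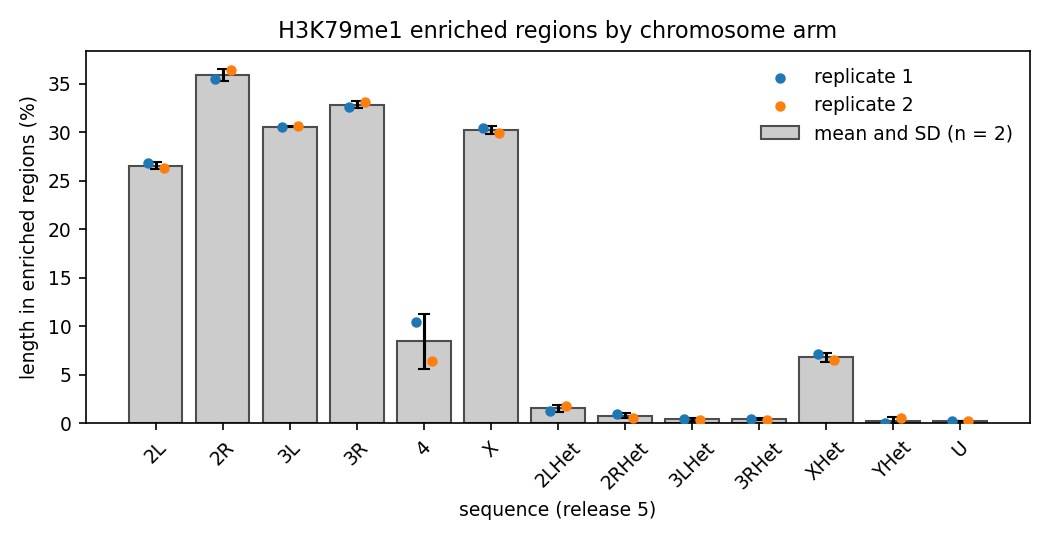
Percent of each sequence of release 5 (x axis) that lay in enriched regions (y axis). Bars show the mean of the replicates, error bars the SD (n = 2) and points each replicate. Uextra, which held no region, is left out. The large arms sit between 26.6% (2L) and 35.9% (2R), and chromosome 4 is at 8.45% ± 2.85.

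**Figure D2:**
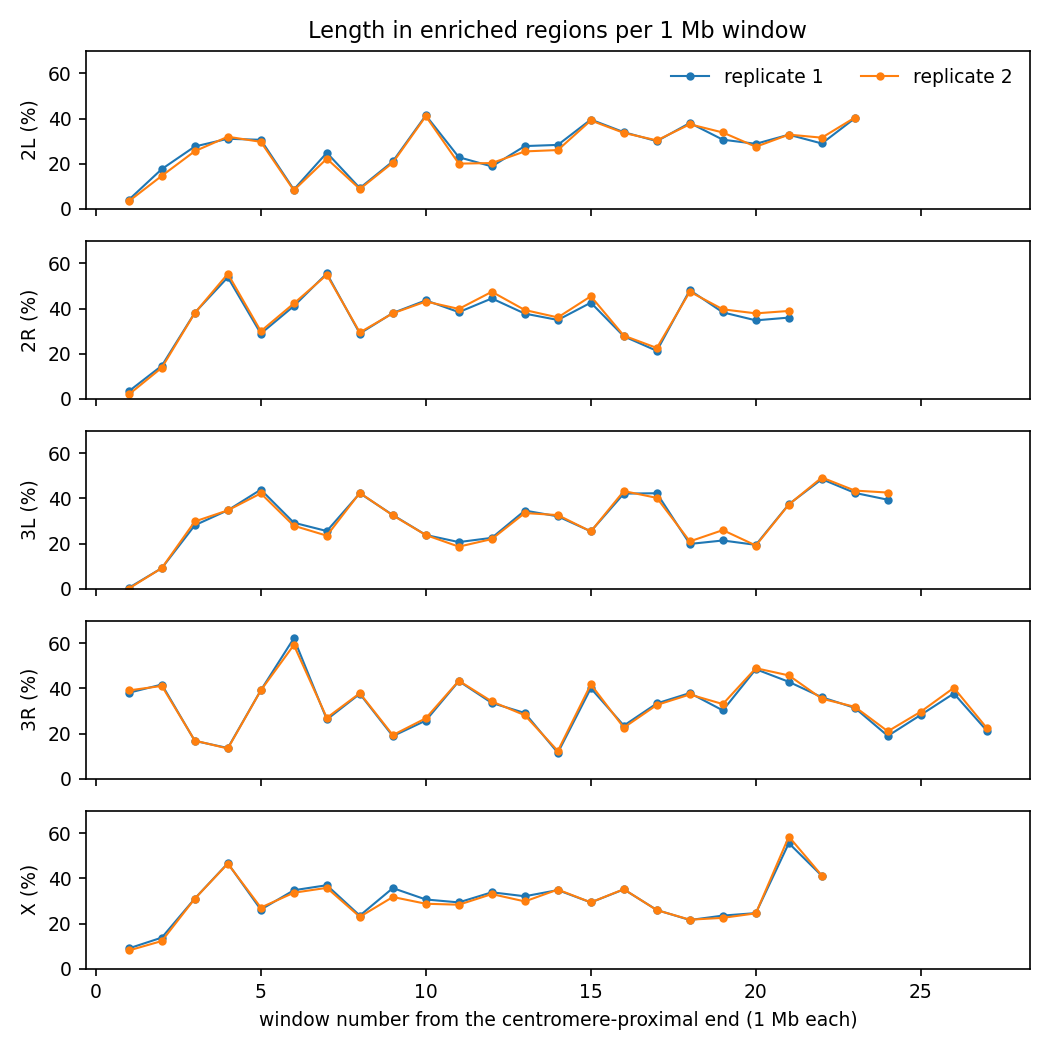
Percent of each full 1 Mb window in enriched regions (y axis) against the number of the window from the centromere-proximal end (x axis), for each large arm, with a line per replicate. The first window is the lowest of its arm on 2L, 2R, 3L and X, at 3.75%, 2.69%, 0.310% and 8.58% in the mean of the replicates, and is at 38.6% on 3R.

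The highest scores of the combined list fell into 2 kinds of region. The first 4 were 1001 bp wide, the minimum width of that list, and no region of either replicate overlapped them. Regions of the replicate lists were at least 1301 bp wide. They lay on 2R at 4289488 to 4290488, 2RHet at 1635930 to 1636930 and 3L at 9570294 to 9571294, each with a score of 3.23, and on 2RHet at 1014120 to 1015120 with a score of 3.04. The other 6 were broad and were found in both replicates over at least 92.7% of their length. Of these, 3R from 20060886 to 20075537 had the highest score, 1.88, followed by X from 11003353 to 11018854 at 1.84 and X from 12579988 to 12589696 at 1.83. X from 2020251 to 2026950 had 1.82, 2L from 183065 to 202128 had 1.82 and X from 10357649 to 10366676 had 1.78.

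The widest region of the combined list spanned 108 kb on X, from 1717108 to 1825183, with a score of 1.28. Replicate 1 covered 96.2% of it in 8 regions and replicate 2 covered 97.6% in 9 regions. The next were 3L from 22295393 to 22399419 (104 kb, score 0.84), 2R from 6911506 to 6994390 (82.9 kb, score 1.32), 2R from 13162151 to 13240065 (77.9 kb, score 1.08) and 2R from 11626864 to 11704213 (77.4 kb, score 0.99). Each was covered over at least 94.5% of its length in both replicates.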

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

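Regions of depletion stood outside the comparisons. Replicate 1 had 0, replicate 2 had 5 and the combined list had 8, of which 3 were in both of the last lists. Their widths were 1449 to 1739 bp in the combined list, and their scores ran from -0.23 to -0.0057. The nearest enriched region of the same list was 86 to 23166 bp away in the combined list and 269 to 7147 bp away in replicate 2. The depletion region of the lowest score lay on 2R from 13343517 to 13345113 in the combined list, and was chosen after its values were seen.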

How the results depend on the processing

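The 250 kb and 1 Mb blocks, the 2 kb minimum width, the distal parts of the arms and the score differences on X were chosen after the data were seen. Of 54 alternative values, 40 kept their direction and their side of the threshold or stayed within a set range. Another 11 moved out of that range, 2 were no longer past the threshold and 1 changed direction. The range was the SD of the replicates, or a fixed factor for counts of regions. For the combined list it was an interval of 77.0% to 78.9%, computed over regions although the share is of base pairs. The Jaccard index stayed between 0.813 and 0.850 under 4 alternatives. Shares of overlapped regions were 76.3% and 66.6% with 50% reciprocal overlap, and rho was 0.87 to 0.93. The X to autosome ratio was 1.04 with regions at or above the median score, and 0.946 and 0.971 with 1 replicate left out. Chromosome 4 ratios were 0.114 to 0.334.

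With regions at or above the median score, which by construction keeps fewer regions, the mean was 3421 regions, 6337 bp median width and 28.8 Mb covered, 73.0% of the combined length lay in both replicates and the heterochromatic share was 0.187%. Merging within 1 kb, which joins neighbours, gave 4361 regions, 4973 bp and 38.4 Mb. The main arms alone gave 37.3 Mb. The heterochromatic share was 0.426% with regions of at least 2 kb and 0.967% in the combined list; the cause was not tested. The planned minimum width of 1 kb removed no region, so its 9 values test nothing and are not counted. No paired analysis was possible because the input libraries had no list here and nothing was tested between groups. Alternatives of the 4 gene results were not run. The depth behind the regions was unknown, and low-scoring regions found in 1 replicate alone cannot be judged by it.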

Other observations

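The ends of the arm sequences on the side of the centromere were poor in H3K79me1 regions on 4 of the 5 large arms. In the last 1 Mb toward the centromere, regions covered 3.75% of 2L, 2.69% of 2R, 0.310% of 3L and 8.58% of X, as means of the replicates, and each was the lowest window of its arm. Medians of the other windows of these arms lay between 29.2% (2L) and 38.3% (2R). On 3R the same window was covered over 38.6%, above the median of 32.4% for its other windows, and ranked 19 of 27 from the lowest. These windows end where the arm sequences of release 5 end, and the heterochromatic sequences are listed apart. That of 3R, 3RHet, was covered over 0.444% ± 0.0782 (SD, n = 2). How far each arm sequence reaches toward its centromere was not examined, so it is open whether 3R is an exception. No test was made of these values, and sequence that tags cannot be placed in counted as not covered.

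Long stretches held no region in any of the 3 lists. On the 6 main arms 177 stretches of at least 100 kb between regions added up to 29999 kb. Stretches from the end of an arm to its first or last region were not counted. The longest counted on each large arm were 2L from 16916937 to 17370573 (454 kb), 2R from 20549 to 435630 (415 kb), 3L from 23329756 to 23736508 (407 kb), X from 20535602 to 20896896 (361 kb) and 3R from 23811419 to 24145509 (334 kb). Those of 2R, 3L and X lay near the centromere-proximal ends described above. These stretches were chosen after their values were seen, and sequence that tags cannot be placed in was not taken out of them.

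The X, chromosome 4 and minimum width patterns below were noticed in the data first. Tests of the spread between arms, of low scores on chromosome 4 and of few tags were chosen after their results or close relatives of them had been seen.

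Regions on X had higher scores than those on the large autosome arms, by 0.0876 in the mean of the replicates (0.79 against 0.71; 2-sided block permutation p = 0.0001, the smallest possible), although a like share of X was covered. Within width bins the difference was 0.0965 (permutation p = 0.0001), which argues against other region widths as the whole cause. Fewer tags on X would raise the lowest score that can be called. Among regions of at least 10 kb the difference was still 0.0966 (permutation p = 0.0001). Width came from the same calling and rose with score, so neither value can decide on fewer tags. Tags per arm and the sex of the larvae were unknown. X stood above the highest autosome arm, 2R, by 0.0450 (block permutation p = 0.038) in the mean of the replicates, by 0.0515 (p = 0.0263) without replicate 1, by 0.0386 (p = 0.0983) without replicate 2 and by 0.0136 (p = 0.676) in the combined list, and over 5 arms the exact p cannot go below 0.2, so an ordinary spread between arms stays open. No biological explanation was tested.

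The low share on chromosome 4 may in part come from enrichment near the calling limit, but the values at hand cannot decide this. Of its regions, 54.3% in replicate 1 (25 of 46; exact 95% interval 39.0% to 69.1%) and 55.9% in replicate 2 (19 of 34; 37.9% to 72.8%) scored below the lower quartile of autosome regions. That quartile, 0.56 and 0.51, is not the calling limit, since the lowest scores called were 0.12 and 0.010. Chromosome 4 regions were also narrower, at medians of 2395 and 2062 bp against 3617 and 3202 bp in the whole lists. Narrower regions had lower scores, and no comparison within widths was made. Sequence on chromosome 4 that tags cannot be placed in was not tested and stays open, and no biological explanation was tested.

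The 4 highest scores of the combined list may rest on few tags. The ratios behind these scores were 8 to 1, 8 to 1, 8 to 1 and 7 to 1 in lowest terms, under the constant that gave the smallest whole numbers over the list. A denominator of 1 occurred in 0.211% of the other regions (16 of 7592), and the median denominator of the other 38 regions of 1001 bp was 156. Another constant would give other ratios and lowest terms hide a common factor, so larger counts stay open, and no biological explanation was tested.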
